A study of Homo sapiens with 8 samples.

How the data were processed

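Expression was measured by RNA sequencing on an Illumina platform in 8 libraries of HT-29 cells, 1 for each of 4 treatments at 24 h and 48 h. Reads were quality-filtered and mapped with HISAT2 version 2.0.5, and the builds GRCh38 and hg38 are named, per the labels' protocols and the submitters' processing notes. The counting tool, the annotation release and the library layout are not given in the sources used here. The deposited gene table holds FPKM values for 60796 genes, with gene lengths and coordinates per the file headers. A second deposited table, whose name speaks of raw counts, holds 1 line per library with counts of sequenced and filtered reads and percent values for base quality and GC content, per the file headers. Filtered reads ranged from 44361052 to 68674126 per library.

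FPKM multiplied by gene length was a whole multiple of 1 step per library, and 100% of values came out whole within a tolerance of 0.01 reads. Recovered reads on genes ranged from 18141663 to 28048517 per library. The steps matched median-ratio size factors times the geometric mean of the totals, so the authors' FPKM denominators were not the library totals. Read ratios carry exact 95% intervals, and a count of 0 allows up to 3 reads. Intervals and limits cover counting error only.

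Before the data were examined, the groups, the tests, the alternatives to try, 37 gene lists and the rule for named genes were fixed. Genes with FPKM of 1 or more in at least 2 of the 8 libraries were tested, 13388 in all. A gene low in the controls could pass through treated libraries alone. Counts of higher members are therefore partly built in for lists that are low in the controls. Values were log2(FPKM + 1), so fold changes of low genes are understated. limma version 3.58.1 in R 4.3.3 was fitted to all 8 libraries with treatment and time as additive terms and a variance trend, which left 3 residual degrees of freedom and a median prior of 5.39. The spread in this fit is how far treatment differences vary between 24 h and 48 h plus library noise, pooled over all 4 treatments. The SE of a contrast therefore also holds the variation of treatments outside it. Tests were two-sided, over 7 contrasts, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Differences at 1 time point come from 1 library against 1 library and were not tested.

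Lists with at least 5 tested members, 32 of them, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. At single times a list's median was placed among 10000 random lists of the same size matched on mean expression.

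Named genes were protein-coding, with mean FPKM of 2 or more and a difference of the same sign and at least 1.5-fold on the log2(FPKM + 1) scale at both times. The 8 highest and 8 lowest by mean difference were named for each treatment against control, and 4 and 4 for the other contrasts. To these were added up to 4 members of each list described, and TYMS, CDKN1A, MDM2, CCNB1, CCND1, BAX, BCL2 and MYC. BCL2 did not pass the filter on low values, and some other genes that the rule named are not reported here.

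The scripts were tested on simulated data for the 5-FU comparison with 12970 genes. Recovered were 10% of genes changed 1.5-fold, 48% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 16 unchanged genes called. A simulated comparison of the 74 3NP extract with the control, with no gene changed, gave 2 calls. The simulation gave every gene the same spread between libraries (dispersion 0.0243) and treatment effects that were equal at 24 h and 48 h. Its changed genes were drawn from genes with many reads. The shares recovered and the false calls therefore do not carry over to real genes, whose effects differ between the times. Alternatives chosen in advance were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, median-ratio scaling, quantile normalization, no variance trend, only the 4 libraries compared, each library left out in turn, no treatment block for the comparison of times, and the other list tests. Added after seeing the data were a loess correction for GC content and gene length, scaling to total reads, and limma voom on the recovered reads. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reading and plotting.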

Results

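RNA was sequenced from HT-29 cells, an established line from a human colorectal adenocarcinoma. The cells were labelled as control, exposed to 5-fluorouracil (5-FU, a drug that blocks thymidylate synthase and is built into RNA and DNA), or exposed to an extract of the rice MRQ 74 or MRQ 76, here called 74 3NP extract and 76 3P extract after the labels. What 3NP and 3P stand for is not given in the sources used here. Groups were taken from the sample titles, which the labels' genotype field matches, while the treatment field names a plant extract for every sample, controls and 5-FU included. Each of the 4 treatments was sampled at 24 h and 48 h with 1 library each, 8 libraries in all. Reads on genes, recovered from the FPKM values, ranged from 18141663 in the 74 3NP extract 48 h library to 28048517 in the 76 3P extract 24 h library. With 1 library per treatment and time, a treatment was tested as its mean difference over both times, so n was 2 libraries per treatment. P-values measure only the spread between these libraries, which nothing in the labels ties to separate cultures.

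The 5-FU 48 h and 76 3P extract 48 h libraries lay farthest from the others on the first principal component, at -58.96 and 42.78, and the control libraries at -1.1 and 6.46. The first component held 44.5% of the variance across 13388 tested genes. Reads from mitochondrial genes made up 6.83% of the 76 3P extract 48 h library and 5.52% of the 5-FU 48 h library, against 2.96% and 3.18% in the controls. The 76 3P extract 48 h library also had 26712 genes above 0, against 23111 to 24665 in the other 7 libraries.

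The first comparison asked what 5-FU, the reference drug, changed. CDKN1A (ENSG00000124762, GRCh38 chromosome 6, 36676460 to 36687337), which encodes the cell cycle inhibitor p21, rose by 1.71 (SE 0.30) on the log2(FPKM + 1) scale, with a limma adjusted p of 0.031. Its FPKM was 101 and 176 with 5-FU at 24 h and 48 h, against 41.4 and 38.9 in the controls. FAS, a death receptor gene, rose by 1.24 (SE 0.22), and MYC, a growth-promoting transcription factor gene, fell by 1.39 (SE 0.31). The genes with the largest tested rises included ECM1 at 2.67 (SE 0.55), RHOV at 2.42 (SE 0.29), VASN at 2.41 (SE 0.29), the elafin gene PI3 at 2.29 (SE 0.47), the water channel gene AQP3 at 2.26 (SE 0.47) and TCAP at 2.15 (SE 0.39). C1RL fell by 2.14 (SE 0.25), HPDL by 2.01 (SE 0.19), LHPP by 2.01 (SE 0.29), TMEM129 by 1.97 (SE 0.19), MGAM2 by 1.92 (SE 0.23) and MAML3 by 1.91 (SE 0.31). CST6 at 2.81, MAB21L4 at 2.16, SLITRK6 at -2.13 and the histone gene H2AW at -2.04 did not pass, with limma adjusted p-values of 0.0667, 0.0588, 0.0546 and 0.0623. Without the 5-FU 48 h library CST6 stood at 1.09, MAB21L4 at 0.98, SLITRK6 at -1.05, ECM1 at 1.56, PI3 at 1.38, AQP3 at 1.46, TCAP at 1.35, MYC at -0.92 and H2AW at -3.08. Without the 5-FU 24 h library CST6 stood at 4.53, MAB21L4 at 3.35, SLITRK6 at -3.21 and H2AW at -0.99, and without a control library MAB21L4 stood at 1.41 and SLITRK6 at -1.38 (control 48 h) and H2AW at -1.23 (control 24 h). TYMS, the gene of thymidylate synthase, was higher by 0.91 (SE 0.29, limma adjusted p 0.0913). BAX at 0.46, MDM2 at 0.56, CCND1 at -0.55 and CCNB1 at 0.24 did not pass.

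Among gene groups fixed in advance, 31 of 36 G1/S and DNA replication genes were higher with 5-FU, with a median log2 difference of 0.68. CDC6 rose by 1.10 (SE 0.26) and RRM2 by 1.05 (SE 0.24), and 6 members rose over all genes tested, against 19 higher and 1 lower adjusted over the list alone. All 16 heat shock genes were higher, with HSPB1 at 1.49 (SE 0.29) and HSP90AA1 at 1.12 (SE 0.25) among the 3 that rose, and 5 did so adjusted over the list alone. All 13 mitochondrially encoded genes were higher, with a median of 0.85, none past the test over all genes and 10 adjusted over the list alone. Of 24 mitochondrial ribosomal and transfer RNAs, 4 rose, among them MT-TL1 by 2.17 (SE 0.27), and 6 adjusted over the list alone. Of 47 cytosolic ribosomal protein genes, 34 were lower, and RPL3 fell by 1.70 (SE 0.21), RPL10A by 1.56 (SE 0.21) and RPL4 by 0.95 (SE 0.22), the same count of 3 adjusted over the list alone. These 5 lists had camera adjusted p-values of 4.54e-07, 0.000392, 2.93e-05, 0.000666 and 8.7e-05 at a preset correlation. With an estimated correlation the adjusted p was 0.765 for the first 4 lists and 0.776 for the ribosomal protein genes. Interferon-stimulated genes were mostly higher, 14 of 17, while their activator STAT2 fell by 1.13 (SE 0.18), and 7 rose and 1 fell adjusted over the list alone. Camera gave an adjusted p of 0.00544, and the adjusted p was 0.765 with an estimated correlation. Of 26 p53 target genes 18 were higher, with 3 past the test, and fry gave an adjusted p of 0.0461 and camera 0.18. Reads of ribosomal protein and mitochondrial genes can be shared with pseudogenes, so those values are uncertain. The mitochondrial ribosomal and transfer RNAs had a median FPKM of 5.76 in the control 24 h library. Transfer RNAs are short, so such values rest on few reads.

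For 5-FU, limma called 336 genes higher and 404 lower, or 257 and 506 with scaling to total reads, with 3885 at an unadjusted p under 0.05 where chance gives 669.4, and voom on the recovered reads called 1150. The count was 0 without the control 24 h, the control 48 h or the 5-FU 48 h library, 20 without the 74 3NP extract 24 h or 48 h library, 2589 without the 5-FU 24 h library, 0 with no filter on low values, 486 with a pseudocount of 5 and 1203 on only the 4 libraries compared.

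The second comparison addressed the 74 3NP extract. CYP1A1 (ENSG00000140465, GRCh38 chromosome 15, 74719542 to 74725536), which encodes an enzyme that oxidises polycyclic aromatic compounds, rose by 3.89 (SE 0.44, limma adjusted p 0.0394), from FPKM 0.932 and 0.988 in the controls to 23.8 and 32.9. SAA1, an acute phase gene, rose by 3.75 (SE 0.43), and the chemokine genes CCL20 and CXCL1 rose by 2.73 (SE 0.26) and 2.25 (SE 0.23). WFDC2, SCAMP5 and EFNA3 rose by 2.13 (SE 0.25), 1.84 (SE 0.19) and 1.77 (SE 0.21), and these were the 7 genes past the test (WFDC2, SCAMP5 and EFNA3 were named after their values were seen). S100A9, a calcium-binding protein gene of inflammation, was higher by 5.00 (SE 0.68, limma adjusted p 0.0682), and the complement gene C3 by 4.23 (SE 0.69, limma adjusted p 0.104). LGALS1 at 3.16, PI3 at 2.71 and PADI3 at 2.56 were also higher. MMP24 at -1.85, SLITRK6 at -1.66, RASD1 at -1.40, GULP1 at -1.34, AVEN at -1.23, PDK4 at -1.16, EDN1 at -1.12 and CCN1 at -1.10 were lower, none past the test. Without the control 48 h library SLITRK6 stood at -0.91, RASD1 at -0.88, PDK4 at -0.49 and EDN1 at -0.40, without the control 24 h library PDK4 at -1.83 and EDN1 at -1.85, and without the extract's 24 h library AVEN stood at -0.73. CDKN1A stood at 0.46, TYMS at -0.63, MYC at 0.36, MDM2 at -0.38, CCND1 at -0.16, BAX at 0.12 and CCNB1 at -0.14, none past the test. SAA1 and the metallothionein genes have close paralogs, so their reads are uncertain.

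Of 16 NF-kB and inflammatory genes, 15 were higher with the 74 3NP extract, with a median of 1.06, and LCN2 stood at 2.37 (SE 0.39). These 16 were the members past the filter of 22 written, whose median FPKM in the control 24 h library was 0.87. Members low in the controls can have passed through treated libraries, so the count of 15 is partly built in. The list had 2 genes past the test over all genes and 11 adjusted over the list alone. The camera adjusted p was 2.48e-11, and the adjusted p was 0.541 with an estimated correlation. Glycolysis and hypoxia genes were higher for 24 of 27 members, with ALDOC at 1.49 (SE 0.30) and CA9, a carbonic anhydrase, at 1.38 (SE 0.36), and 1 passed adjusted over the list alone. By camera the adjusted p was 1.81e-08, and the adjusted p was 0.541 with an estimated correlation. Cholesterol synthesis genes were higher for 20 of 22, with DHCR7 at 0.92 (SE 0.24), and 3 passed adjusted over the list alone. For this list the camera adjusted p was 0.000114, and the adjusted p was 0.541 with an estimated correlation. All 6 metallothionein genes were higher, MT1A at 1.90 (SE 0.41) and MT1G at 1.67 (SE 0.48), with 3 adjusted over the list alone. Camera gave an adjusted p of 0.00015, and the adjusted p was 0.541 with an estimated correlation. G2/M genes were lower for 28 of 31, with a median of -0.38 and 0 past either limma adjustment, over all genes or adjusted over the list alone. The camera adjusted p was 0.000493, and the adjusted p was 0.806 with an estimated correlation. After a correction for GC content and gene length the G2/M median was -0.18, with a camera adjusted p of 0.0133.

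Limma pooled the spread over all 4 treatments, so the test of the 74 3NP extract also carried the spread of the others. Across genes the log2 differences between 48 h and 24 h had an SD of 0.365 for this extract. The SD was 0.517 for 5-FU, 0.537 for the 76 3P extract and 0.291 for the controls. The 7 calls with the 74 3NP extract, from 1623 genes at an unadjusted p under 0.05, became 25 with a filter at FPKM 5, 17 with voom, 1344 on only the 4 libraries compared, 1 with a pseudocount of 5, and 0 with no filter, quantile normalization, no variance trend or a correction for GC content and length. The count was 2 without the control 24 h library, 0 without the control 48 h, 5-FU 24 h, 5-FU 48 h or 74 3NP extract 24 h library, 1 without the 74 3NP extract 48 h library, and 107 and 104 without the 76 3P extract 24 h and 48 h libraries, and a simulated comparison with no change gave 2 calls.

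The third comparison addressed the 76 3P extract, where limma called 0 genes. CYP1A1 was higher by 4.33 (SE 0.44, limma adjusted p 0.0536), with FPKM 17.7 at 24 h and 81.8 at 48 h. SAA1 stood at 3.00 (SE 0.43), C3 at 2.52 (SE 0.69), NGFR at 2.29 (SE 0.56), the stress transcription factor gene ATF3 at 2.20 (SE 0.37), DHRS2 at 2.17 (SE 0.32), SNAI1 at 2.05 (SE 0.64) and LCN2 at 2.04 (SE 0.39). TYMS (ENSG00000176890, GRCh38 chromosome 18, 657653 to 673578) was lower by a log2 difference of -1.85 (SE 0.29, limma adjusted p 0.0653), with FPKM 4.12 and 1.97 against 12.01 and 14.27 in the controls. CLDN2, a tight junction gene, stood at -2.34 (SE 0.32), SLITRK6 at -2.33 (SE 0.53), ANXA10 at -2.16 (SE 0.23), TSPAN8 at -2.08 (SE 0.39), FAM111B at -2.01 (SE 0.25), PCLAF at -1.99 (SE 0.35) and the helicase gene MCM4 at -1.88 (SE 0.24). CDKN1A was higher by 1.18 (SE 0.30), CCNB1 stood at -1.09 (SE 0.39), CCND1 at -0.41, BAX at -0.35, MDM2 at -0.30 and MYC at 0.03, none past the test. Both means leaned on the 48 h library, with CDKN1A at 0.75 and 1.6 and CCNB1 at -0.68 and -1.5 at 24 h and 48 h. Without the 76 3P extract 48 h library C3 stood at 0.93, NGFR at 1.03, SNAI1 at 0.60 and LCN2 at 1.35, and without its 24 h library C3 stood at 4.10, NGFR at 3.55 and SNAI1 at 3.49.

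All 36 G1/S and DNA replication genes were lower with the 76 3P extract, with a median of -1.19, UHRF1 at -1.80 (SE 0.25) and MCM5 at -1.73 (SE 0.22), and 34 passed adjusted over the list alone. By camera the adjusted p was 7.23e-29, and the adjusted p was 0.477 with an estimated correlation. All 31 G2/M genes were lower, with the proliferation marker MKI67 at -1.35 (SE 0.19) and CENPF at -1.47 (SE 0.21), and 21 passed adjusted over the list alone. For this list the camera adjusted p was 1.66e-14, and the adjusted p was 0.477 with an estimated correlation. DNA repair genes were lower for 21 of 23, with BLM at -1.28 (SE 0.20), and 17 passed adjusted over the list alone. Camera gave an adjusted p of 5.9e-11, and the adjusted p was 0.477 with an estimated correlation. NF-kB and inflammatory genes were higher for 15 of 16, with CCL20 at 1.96 (SE 0.26), and 14 passed adjusted over the list alone. As with the 74 3NP extract, the filter can partly build in the results of this list. The camera adjusted p was 1.75e-12, and the adjusted p was 0.474 with an estimated correlation. Integrated stress response and ER stress genes were higher for 22 of 25, with DDIT4 at 1.99 (SE 0.35), DDIT3 at 1.92 (SE 0.65) and HERPUD1 at 1.78 (SE 0.53), and 11 passed adjusted over the list alone. DDIT3 and HERPUD1 leaned on the extract's 48 h library. Without it their differences of the 74 3NP from the 76 3P extract went from -2.66 to -1.63 and from -2.26 to -1.08. Without the 24 h library HERPUD1 went to -3.44. By camera the adjusted p was 1.88e-08, and the adjusted p was 0.477 with an estimated correlation. All 16 immediate early genes were higher, with FOS at 1.44 (SE 0.41), and 10 passed adjusted over the list alone. For this list the camera adjusted p was 9.98e-10, and the adjusted p was 0.477 with an estimated correlation. Of 23 MYC and ribosome biogenesis genes 22 were lower, 3 of them adjusted over the list alone, with a camera adjusted p of 6.17e-05 and an adjusted p of 0.474 with an estimated correlation. Fry called 3 lists, each at an adjusted p of 0.0482, the G1/S genes, the MYC and ribosome biogenesis genes and the p53 target genes, of which 17 of 26 were higher with a camera adjusted p of 0.12.

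Beside the 0 calls of limma, 2356 genes had an unadjusted p under 0.05 and voom called 184, a filter at FPKM 5 gave 160, the 4 libraries alone gave 288, and pseudocounts of 0.1 and 5 gave 3 and 2. The count was 803 without the 76 3P extract 24 h library and 2 without the control 24 h library.

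The extracts were then compared with each other. ATF3 was lower with the 74 3NP extract than with the 76 3P extract by a log2 difference of -3.15 (SE 0.37, limma adjusted p 0.058), and DDIT3 at -2.66 (SE 0.65), HERPUD1 at -2.26 (SE 0.53) and LAMP3 at -2.25 (SE 0.25) were lower too. S100A9 at 2.97 (SE 0.68), the keratin gene KRT6B at 2.41 (SE 0.32), CEMIP at 2.35 (SE 0.33) and ANXA10 at 2.06 (SE 0.23) were higher with the 74 3NP extract. Without the 76 3P extract 48 h library DDIT3 stood at -1.63 and HERPUD1 at -1.08, and without its 24 h library S100A9 stood at 1.56 and HERPUD1 at -3.44. All 36 G1/S genes were higher with the 74 3NP extract, with a median of 0.95 and 31 adjusted over the list alone. Camera gave an adjusted p of 3.11e-28, and the adjusted p was 0.409 with an estimated correlation. All 25 integrated stress response and ER stress genes were lower, with a median of -1.05 and 14 adjusted over the list alone. The camera adjusted p was 1.84e-15, and the adjusted p was 0.409 with an estimated correlation. MYC and ribosome biogenesis genes were higher for 22 of 23, with 9 adjusted over the list alone, and fry gave an adjusted p of 0.0223. By camera the adjusted p was 3.23e-08, and the adjusted p was 0.303 with an estimated correlation. Single genes past the limma test numbered 0, with 1726 at an unadjusted p under 0.05, 26 by voom and 16 with a filter at FPKM 5. The count was 79 without the 76 3P extract 24 h library, 4 without the 76 3P extract 48 h library, 2 without the 74 3NP extract 24 h library and 1 without the 5-FU 24 h or 48 h library.

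Each extract was also set against 5-FU. With the 74 3NP extract C3 rose by 4.19 (SE 0.69), CYP1A1 by 3.48 (SE 0.44), LGALS1 by 3.06 (SE 0.51) and S100A9 by 3.04 (SE 0.68) relative to 5-FU. SDCBP2 fell by 2.49 (SE 0.44), MAB21L4 by 2.37 (SE 0.56), ATF5 by 2.17 (SE 0.35) and VASN by 2.15 (SE 0.29). With the 76 3P extract CYP1A1 rose by 3.92 (SE 0.44), DDIT4 by 3.24 (SE 0.35), DHRS2 by 3.22 (SE 0.32) and UNC5B by 2.80 (SE 0.51). FAM111B fell by 2.89 (SE 0.25), ANXA10 by 2.80 (SE 0.23), ECM1 by 2.77 (SE 0.55) and TYMS by 2.77 (SE 0.29). Without the 5-FU 48 h library the differences were -1.57 for SDCBP2 and -1.19 for MAB21L4 with the 74 3NP extract and -1.66 for ECM1 with the 76 3P extract, and UNC5B stood at 1.83 without the 76 3P extract 48 h library. With the 76 3P extract 33 of 36 G1/S genes fell relative to 5-FU past the test over all genes, and 35 did adjusted over the list alone, with a median of -1.82. For this list the camera adjusted p was 6.46e-23, and the adjusted p was 0.687 with an estimated correlation. Fry gave an adjusted p of 0.0222 for it and 0.013 for goblet and secretory cell genes, 4 of 6 lower with a camera adjusted p of 0.205. For the 74 3NP extract 19 of the 36 fell past the test over all genes, and 26 adjusted over the list alone, with a median of -0.84. Camera gave an adjusted p of 4.29e-09, and the adjusted p was 0.576 with an estimated correlation. Of 26 p53 target genes 19 were lower with this extract, where 4 fell and 1 rose and 9 and 1 did adjusted over the list alone, with adjusted p-values of 0.00314 by fry, 0.0165 by camera and 0.557 by camera with an estimated correlation. Limma called 817 genes higher and 628 lower for the 74 3NP extract, and 1176 higher and 1411 lower for the 76 3P extract, where scaling to total reads turned the balance to 1452 higher and 1028 lower. No filter gave 0 in both, and with the filter the unadjusted counts were 4277 and 5124 and voom called 1867 and 3203. Without 1 library the 74 3NP extract count was 517 (control 24 h), 536 (control 48 h), 2565 (5-FU 24 h) or 0 (5-FU 48 h, 74 3NP extract 24 h or 48 h), and the 76 3P extract count 1363 (control 24 h), 1362 (control 48 h), 298 (5-FU 48 h), 1538 and 1508 (74 3NP extract 24 h and 48 h) or 178 (76 3P extract 48 h).

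Between 48 h and 24 h, which the labels also name as batches so that time and batch cannot be separated, and averaged over the 4 treatments, WFDC2 was higher by 1.47 (SE 0.18), the hypoxia gene NDRG1 by 1.41 (SE 0.18), EFNA3 by 1.08 (SE 0.15) and MDK by 0.99 (SE 0.14), and PRSS2, which has close paralogs, stood at -1.21 (SE 0.18). Glycolysis and hypoxia genes were higher for 23 of 27 and 6 passed adjusted over the list alone. The camera adjusted p was 5.57e-07, and the adjusted p was 0.617 with an estimated correlation. All 13 replication-dependent histone genes, which also have close paralogs, were higher, with 2 adjusted over the list alone. By camera the adjusted p was 2.47e-06, and the adjusted p was 0.768 with an estimated correlation. Medians were also 0.43 for mitochondrially encoded genes, 0.48 for mitochondrial ribosomal and transfer RNAs and -0.27 for MYC and ribosome biogenesis genes. After the correction for GC content and gene length their camera adjusted p-values were 2.85e-06, 1.61e-07 and 7.04e-07. With an estimated correlation 0 lists passed, and the cause of these shifts was not tested. The shifts were uneven across treatments. From 24 h to 48 h the share of reads on mitochondrial genes went from 2.98% to 6.83% with the 76 3P extract. It went from 3.12% to 4.07% with the 74 3NP extract, from 4.62% to 5.52% with 5-FU and from 2.96% to 3.18% in the controls. The histone median with 5-FU against the control changed sign between the times, to 0.35 at 48 h. Single genes past the limma test numbered 0, with 1394 at an unadjusted p under 0.05, 2 by voom and 2 with a filter at FPKM 5.

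At single times there was no test and no replicate check. With 5-FU 574 genes differed at least 2-fold from the control at 24 h and 2100 at 48 h. With the 74 3NP extract the numbers were 601 and 421, and with the 76 3P extract 351 and 1365. The control libraries differed from each other at least 2-fold for 158 genes. These numbers depend on the pseudocount of 1, and for 5-FU at 24 h the number was 1501 with 0.1 and 89 with 5. Across genes, which are not independent replicates, the differences at 24 h and 48 h correlated with Pearson's r of 0.616 for 5-FU, 0.60 for the 74 3NP extract and 0.538 for the 76 3P extract. Genes changed 2-fold at both times had the same direction for 310 of 331 with 5-FU, 194 of 209 with the 74 3NP extract and 171 of 187 with the 76 3P extract. Between different treatments r ranged from 0.053 for 5-FU at 24 h and the 76 3P extract at 48 h, with 87 of 125 genes in the same direction, to 0.496 for the 74 3NP extract at 24 h and the 76 3P extract at 48 h, with 301 of 318. The reverse pairing, the 76 3P extract at 24 h and the 74 3NP extract at 48 h, had an r of 0.264, with 55 of 78. Independent lists would share 10.5 higher and 1.2 lower genes between the times of the 74 3NP extract, against 183 and 11 observed. NF-kB and inflammatory genes had medians of 1.22 and 0.77 with the 74 3NP extract and 1.09 and 1.32 with the 76 3P extract at 24 h and 48 h, each at percentile 100 of 10000 random lists matched on expression. The match was on the mean over all 8 libraries, treated ones included. Members that passed the filter through treated libraries can therefore partly build in these percentiles. For CYP1A1 the reads at 48 h with the 76 3P extract were 7194 against 76 in the control, a ratio of 82.8 with an exact 95% interval of 66.1 to 105, which covers counting error only and compares those libraries.

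**Figure D1:**
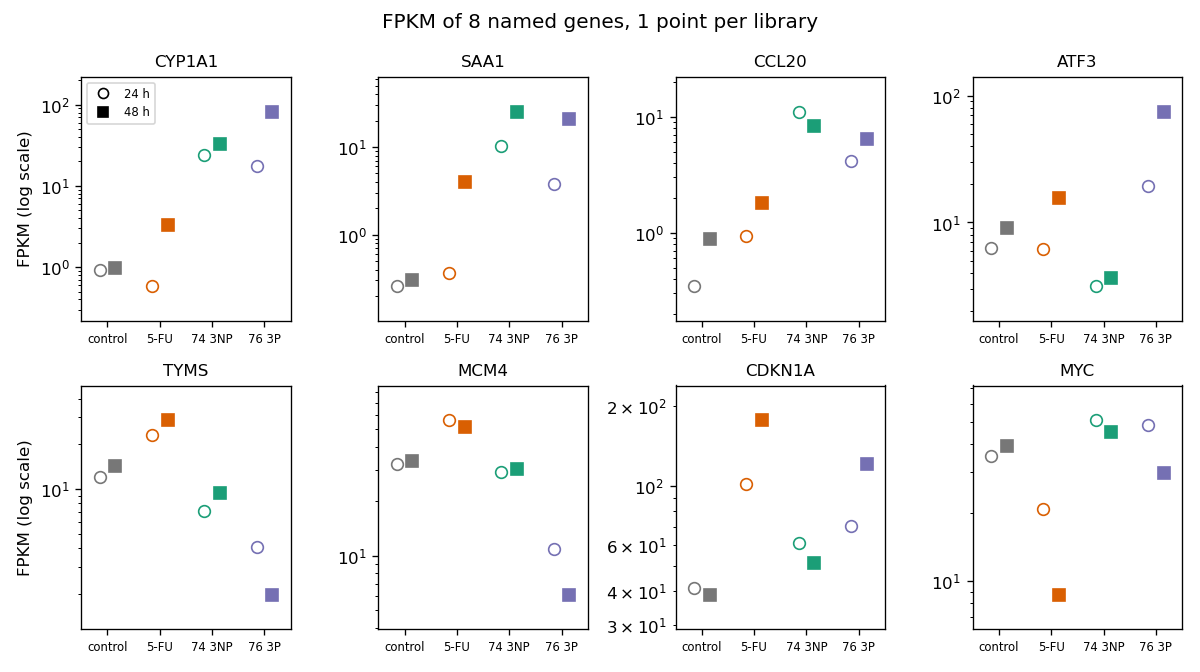
FPKM of 8 named genes on log axes by treatment, 1 point per library, with open circles for 24 h and filled squares for 48 h. CYP1A1 stands at 81.8 in the 76 3P extract 48 h library and below 1 in both controls.

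**Figure D2:**
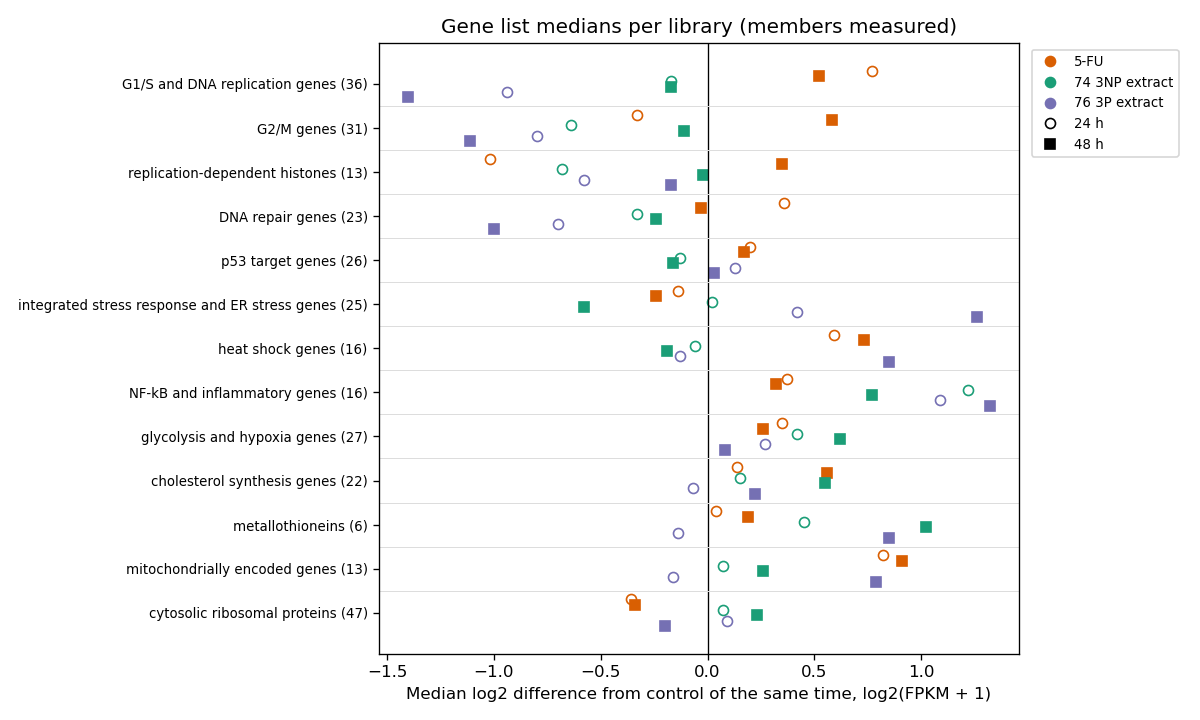
Median log2 difference from the control of the same time for gene lists fixed in advance, on the log2(FPKM + 1) scale, with open circles for 24 h and filled squares for 48 h, each from 1 library against 1 control, and the members measured in brackets. The G2/M genes stand at -0.33 at 24 h and 0.58 at 48 h with 5-FU.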

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

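The tests of library depth, genomic DNA and cells of another type, with their bounds, the correction for GC content and gene length and the comparison of 5-FU with the control of the other time were chosen after the result was seen. At single times every difference below rests on 1 library against 1 control, and none was tested between the times.

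The 76 3P extract 48 h library held reads on genes that had none in either control, 14482 reads against 4667 at 24 h with the same extract, and more genes above 0 than any other library. Thinned to 18141663 reads per library, it still had 25804 genes above 0, against at most 23836 in the other 7, which argues against library depth. The share of reads on 381 olfactory receptor genes was 1 times that at 24 h (exact 95% interval 0.81 to 1.24), against 3.51 for the genes silent in controls, which argues against genomic DNA as the source of the excess over 24 h, although the libraries of this extract had 6.67 RPM (24 h) and 6.69 RPM (48 h) on these receptor genes, against 2.9 to 5.43 in the other 6. Cells of another type cannot be told apart from a response of the HT-29 cells: of the fixed marker lists the endothelial list had the largest share above both controls, 50% of 8 genes, with 46.2% for leukocyte and hepatocyte genes and 36.4% for fibroblast genes. Reads were 0 for 7 of 11 fibroblast, 4 of 13 leukocyte, 5 of 13 hepatocyte and 3 of 8 endothelial genes, with COL1A2, PTPRC, ALB and CDH5 among them and among a first set of 8 genes picked after their values were seen, while COL1A1 and CD14 stood at FPKM 6.21 and 9.83 there, against 1.35 and 1.86 in the control at 48 h and 3.51 and 6.41 with the 74 3NP extract at 48 h, and LYZ at 215 against 384 and 601.

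NF-kB and inflammatory genes were higher with both extracts, and the reads of 5 libraries had a GC content above both controls, at 53.22% for 5-FU 48 h, 53.94% and 52.59% for the 74 3NP extract and 53.1% and 53.02% for the 76 3P extract at 24 h and 48 h. Across genes, which are not independent replicates, the difference from control correlated with GC content, with Spearman's rho of 0.56 and 0.34 for the 74 3NP extract and 0.37 and 0.21 for the 76 3P extract. With 5-FU rho was 0.07 at 24 h and 0.21 at 48 h. For the control 48 h library against the control 24 h library it was 0.27, so a GC trend was not particular to the extracts. After a correction for GC content and gene length the median of the list was 0.95 with the 74 3NP extract, from 1.06, and 1.26 with the 76 3P extract, from 1.31, which argues against that trend as the whole source. The correction ended the 2 calls within the list: CCL20 went from 2.73 (SE 0.26) to 3.01 (SE 0.33) and CXCL1 from 2.25 (SE 0.23) to 2.22 (SE 0.25), with the limma adjusted p at 0.149 for both, while the prior degrees of freedom went from 5.39 to 4.05 and the genes at an unadjusted p under 0.05 from 1623 to 1252, and the parts of these and of the SE were not separated. A biological response to the extracts stays open and may account for it.

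G2/M genes were lower with 5-FU at 24 h, with a median of -0.33, and higher at 48 h, at 0.58, and CCNB1 stood at -0.31 and 0.79. After the correction for GC content and gene length the medians were -0.33 and 0.59, which argues against that bias. The gap between the 5-FU medians was 0.92. From 24 h to 48 h the median difference was -0.25 in the control libraries and 0.52 in the 5-FU libraries. These medians do not add up to the gap, so it cannot be split between them. The -0.25 fell between the bounds fixed in advance, so the test of a difference between the 2 control libraries could not tell. Against the control of the other time the 5-FU medians were 0 at 24 h and 0.43 at 48 h, so for the lower value at 24 h a difference between the control libraries cannot be told apart from a change with time under 5-FU, as each time has 1 control. A biological change with time stays open, untested.

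Other medians or values also had opposite signs at 24 h and 48 h. With 5-FU the medians at 48 h were 0.01 for anti-apoptotic genes, 0.35 for replication-dependent histones (-1.02 at 24 h), -0.02 for nucleotide and 5-FU metabolism genes, -0.03 for DNA repair genes, -0.52 for fatty acid oxidation and PPAR targets and 0.36 for epithelial genes. With the 74 3NP extract they were 0.03 for CDK inhibitors, -0.58 for integrated stress response and ER stress genes, -0.50 for NRF2 antioxidant genes, 0.21 for interferon-stimulated genes and -0.03 for immediate early genes, and BAX stood at -0.10 and CCNB1 at 0.08. With the 76 3P extract they were -0.01 for pro-apoptotic genes, 0.85 for heat shock genes, 0.85 for metallothioneins, 0.22 for cholesterol synthesis genes, -0.35 for fatty acid oxidation and PPAR targets, 0.48 for interferon-stimulated genes, -0.20 for cytosolic ribosomal proteins, -0.25 for nuclear-encoded respiratory chain genes, 0.79 for mitochondrially encoded genes, 0.52 for absorptive enterocyte genes, -0.14 for epithelial genes and -0.12 for mesenchymal transition genes, and BAX stood at -0.93 and MYC at -0.38.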

How the results depend on the processing

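The fit already set each treatment against the control of the same time, with time as a block. No paired analysis by replicate number could be added, because the groups share only the replicate number 1. The GC and length correction, total-read scaling and voom were chosen after seeing the data. Where 1 library was left out, the lone library of that treatment was assumed to vary like the others. For 441 named gene effects, 7217 of 8331 values kept their direction and side of the threshold, 668 lost the call, 423 gained it and 23 changed sign. Where no cause is given, the cause was not tested.

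A pseudocount of 0.1 gave 3 calls with the 76 3P extract against control. It raised the numbers changed 2-fold at 24 h and 48 h to 1501 and 3622 for 5-FU, 1433 and 1040 for the 74 3NP extract, 976 and 2388 for the 76 3P extract, and 1006 and 1891 between the extracts, and the agreement of the times for the 74 3NP extract went to 0.474. A pseudocount of 5 gave 486 calls for 5-FU, 1 for the 74 3NP extract and 2 for the 76 3P extract, and 2-fold numbers of 89 and 749, 102 and 82, 48 and 404, and 76 and 301 in the same order, since it shrinks low genes. No filter gave 0 calls in limma for 5-FU, for the 74 3NP extract and for each extract against 5-FU, with 33187 genes tested and a prior of 2.05 degrees of freedom. A filter at FPKM 5 (8059 genes) gave 25, 160, 16 and 2 calls for the 74 3NP extract, the 76 3P extract, the extracts compared and 48 h against 24 h, and 2-fold numbers of 310 for 5-FU at 24 h, 305 and 198 for the 74 3NP extract, 193 and 821 for the 76 3P extract and 195 and 647 between the extracts. For the 74 3NP extract quantile normalization, the GC and length correction and no variance trend each gave 0 calls. Under the GC and length correction its adjusted p-values were 0.149 to 0.152, with CYP1A1 from 3.89 (SE 0.44) to 3.78 (SE 0.46), SAA1 from 3.75 (SE 0.43) to 3.61 (SE 0.45), WFDC2 from 2.13 (SE 0.25) to 1.95 (SE 0.24), EFNA3 from 1.77 (SE 0.21) to 1.51 (SE 0.17) and SCAMP5 from 1.84 (SE 0.19) to 1.70 (SE 0.18). Only the 4 libraries compared gave 1203, 1344 and 288 calls for 5-FU, the 74 3NP extract and the 76 3P extract, and voom 1150, 17 and 184, with 26 between the extracts and 2 for time. Total-read scaling moved the share of higher calls from 45.4% to 33.7% for 5-FU and from 45.5% to 58.5% for the 76 3P extract against 5-FU, where the median of all genes went from -0.036 to 0.072.

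Camera called 9, 13, 12, 20, 17, 10 and 9 lists for 5-FU, the 74 3NP extract, the 76 3P extract, the extracts compared, the 74 3NP extract and the 76 3P extract against 5-FU, and time. An estimated correlation, with only 3 residual degrees of freedom behind it, left 0 in each, and fry gave 1, 0, 3, 3, 1, 2 and 0.

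With 1 library left out, calls ranged from 0 to 2589 for 5-FU, 0 to 107 for the 74 3NP extract, 0 to 803 for the 76 3P extract, 0 to 79 between the extracts, 0 to 2565 for the 74 3NP extract against 5-FU and 178 to 3644 for the 76 3P extract against 5-FU, and stayed at 0 for time. Called lists ranged from 9 to 14, 8 to 14, 11 to 16, 13 to 20, 13 to 17, 7 to 14 and 7 to 9 in the order above.

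These named genes changed sign. Quantile normalization gave CCNB1 -0.044 with 5-FU. The GC and length correction gave BAX -0.116 with the 74 3NP extract, MYC -0.018 with the 76 3P extract and MDM2 0.012 between the extracts. With 1 library left out, CCNB1 ranged from -0.376 to 0.857 with 5-FU, negative without 5-FU 48 h. With the 74 3NP extract, BAX ranged from -0.127 to 0.371 and MYC from -0.051 to 0.763, negative without control 24 h. UGT1A6 ranged from -0.967 to 0.072, positive without control 48 h, and CCNB1 from -0.317 to 0.033, positive without the extract's 24 h library. With the 76 3P extract, MYC ranged from -0.375 without control 24 h to 0.439, and was -0.106 without the extract's 24 h library. IFI6 ranged from -0.031 without control 48 h to 1.571. Without the extract's 48 h library BAX turned positive, from -0.87 to 0.174 over all, and MT-ND4L (-0.097 to 1.089), MT-ND5 (-0.071 to 1.015) and MT-ND4 (-0.145 to 0.891) turned negative. Between the extracts, MDM2 ranged from -0.255 to 0.101, positive without 74 3NP extract 24 h. MT-TH ranged from -2.98 to 0.247, positive without 74 3NP extract 48 h. Without 76 3P extract 48 h BAX (-0.052 to 0.991) and NDUFB3 (-0.009 to 1.031) were negative and HSPA1A (-2.591 to 0.042) positive. For time, HMOX1 ranged from -0.086, without either 76 3P extract library, to 1.212.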

Other observations

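The tests of aryl hydrocarbon receptor targets and the correction for GC content and gene length were chosen after the result was seen. Further list results not described above include autophagy and lysosome genes with the 76 3P extract, where GABARAPL1 stood at 1.31 (SE 0.22) and WIPI1 at 1.29 (SE 0.23), with 13 of 20 members higher and 3 past limma adjusted over the list alone. For this list the camera adjusted p was 0.0404, and the adjusted p was 0.686 with an estimated correlation. Against the 76 3P extract, the 74 3NP extract had 15 of 26 p53 target genes lower, with a median of -0.11, GADD45A at -1.59 (SE 0.27), SESN2 at -1.36 (SE 0.28) and BBC3 at -1.16 (SE 0.20), and 5 adjusted over the list alone. Camera gave an adjusted p of 0.00456, and the adjusted p was 0.409 with an estimated correlation, and fry gave an adjusted p of 0.00618. Goblet and secretory cell genes were higher for 5 of 6, with SPDEF at 1.57 (SE 0.20) and 2 adjusted over the list alone. The camera adjusted p was 0.0382, and the adjusted p was 0.409 with an estimated correlation, and fry gave an adjusted p of 0.00944. After the correction for GC content and gene length the camera adjusted p for this list was 0.0717 and its median went from 0.28 to 0.19.

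Activation of the aryl hydrocarbon receptor may account for the higher CYP1A1 and CYP1B1 with both extracts, CYP1B1 standing at 1.31 (SE 0.24) with the 74 3NP extract and 1.35 (SE 0.24) with the 76 3P extract. Of 7 other targets, 2 were higher than their control at both times with both extracts, where 17.4% of all tested genes were, so the test of aryl hydrocarbon receptor activation decided nothing.

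For 48 h against 24 h, the libraries can be split 4 against 4 in 35 ways, 32 of which could be fitted with the treatment block. The real split gave 0 genes past the limma threshold and the highest other split 1, and since any split gives at least 0, the count of 32 of 32 with as many decides nothing. At an unadjusted p under 0.05 the real split gave 1394 genes and the highest other 2079. In all, 5 splits, the real one included, gave as many. The others of these kept both libraries of 2 treatments on the same side, so their effect rested on the remaining treatments. The count of 2079 came from setting 48 h against 24 h within those remaining treatments, so it cannot stand for a split unrelated to time. Among splits that divided every treatment, the real one gave the most genes and the next 809. Such splits were few, so this rank decides nothing. Voom called 2 genes for the real split.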
